A study of Homo sapiens with 78 samples.

How the data were processed

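Gene expression was measured with Affymetrix expression arrays in 2 blood cell fractions, granulocytes and peripheral blood mononuclear cells (PBMC), from patients with juvenile idiopathic arthritis (JIA) in remission and from healthy controls. Patients took methotrexate (MTX) alone or MTX with etanercept, a soluble TNF receptor that binds the cytokine TNF (MTX+Et). The 78 arrays fell into 6 groups. Among granulocytes there were 13 healthy, 10 MTX and 12 MTX+Et samples, and among PBMC 15 healthy, 14 MTX and 14 MTX+Et samples. Per the labels, the fractions came from a density gradient, red cells were lysed, and total RNA was purified and labelled as biotin cRNA. The labels do not link a granulocyte sample to a PBMC sample, so all samples were treated as independent.

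The deposited values are log2 signals per probe set, made by the authors with RMA (robust multi-array average) in Affymetrix Expression Console, per the submitters' processing notes, which give no version. RMA corrects background, applies quantile normalization and summarises probes. The deposited table held 54675 probe sets. The mean array median was 4.60 in healthy granulocytes and 5.14 in healthy PBMC, so the 2 cell types did not share 1 distribution of values. For arrays the number of samples limits the precision, and a dim gene is limited by signal over background.

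Probe sets were joined to genes by the symbol in the platform annotation. A single symbol was given for 41097 probe sets, 1801 listed several and 11777 had none here, and 41032 probe sets with a symbol found in the gene reference were used, for 19740 genes. No genome build is attached to the values, so no coordinates are given. Each gene was represented by its probe set with the highest mean over the samples of a cell type, and the lowest 40 percent of genes by mean were left out. That kept 11844 genes in each cell type, with a lowest mean log2 signal of 4.71 in granulocytes and 5.18 in PBMC. Genes on the Y chromosome and genes of X inactivation were left out of every table.

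Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with version 1.17.8 of data.table and jsonlite 2.0.0 for reading files and matplotlib 3.10.9 for figures. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. The description label gives each array a code that opens with E, F or H, and the labels do not say what the letter stands for. A rule fixed beforehand kept the letter as a covariate if it called over 1 percent of genes. It called 38.2 percent in granulocytes and 45.1 percent in PBMC, so the letter was in every fit that is reported. Among healthy samples alone, F and E arrays differed in 1689 genes (14.3 percent) in granulocytes and in 5528 genes (46.7 percent) in PBMC. In granulocytes E, F and H arrays numbered 6, 7 and 0 for healthy, 5, 1 and 4 for MTX, and 3, 1 and 8 for MTX+Et. In PBMC they numbered 7, 8 and 0 for healthy, 3, 2 and 9 for MTX, and 1, 2 and 11 for MTX+Et.

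Per cell type, MTX was compared with healthy, MTX+Et with healthy and MTX+Et with MTX. Whether an effect differed between cell types was tested as an interaction (effect in PBMC minus effect in granulocytes) over 10640 genes kept in both. Calls shared by both regimens were set against 100 simulated draws of unchanged groups that share the healthy samples, against the product of the counts, and against 20 splits of the healthy samples into separate parts. For 28 gene lists of cell types, pathways and drug handling, camera in limma was run with its preset correlation of 0.01 and again with an estimated correlation. The preset treats the genes of a list as nearly independent, so its p-values can be too small where the genes vary together. Adjustment was over the lists of a comparison, and member counts were also adjusted over the list alone. The comparisons, the covariate rule, the lists, the rule for named genes and the first set of alternatives were chosen before the data were examined.

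Named genes were the 12 largest rises and 12 largest falls past the threshold, up to 4 passing members of each list, and TNF, its receptors and genes of folate handling whether or not they passed. Where under 5 genes passed, the 5 genes of each direction with the smallest unadjusted p were named as values. The same rule was applied again without 1 PBMC array with a narrow range of values, after the data had been examined, and genes added that way are marked in the text. Counts of samples above or below another group's mean were taken after the letter term was removed. No healthy array carries H, so in comparisons with healthy the fit itself sets where the patient H arrays lie on average. There these counts are no check of single samples by themselves. Values under a single letter are given only where both groups held at least 2 arrays of that letter.

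The alternatives were no letter term, no filter on dim genes, a filter of 60 percent, the mean of a gene's probe sets, all probe sets, quantile normalization within a cell type, centring on the median, array weights, eBayes with trend and robust options, the replicate number as a block, 6 groups in 1 fit, 2 groups only, a change of at least 1.5-fold, E, E and F, or H arrays alone, and, between the regimens, the leading digits of the code with the letter as covariate. Others were added after the data had been examined: F arrays alone, PBMC without the narrow-range array, the same without the letter, the 3' minus 5' signal difference of ACTB and GAPDH or the mean of the T cell list as a covariate, and each array left out in turn, for the counts of genes and for the lists with the preset correlation. The reported fits, the PBMC fits without the narrow-range array and the interaction fits were tested on simulated data with known changes; the other alternatives were not. The share of simulated 2-fold changes that was called ranged from 80.6 to 97.0 percent over the 6 comparisons within a cell type, and from 52.2 to 86.6 percent for 1.5-fold changes. The simulated noise was drawn for each gene separately, without shifts shared by genes or particular to 1 array, and many genes were changed at once. These shares are therefore no measure of the power of the real fits, and a low count of called genes is not shown to be well powered.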

Results

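Gene expression was profiled on 78 arrays from granulocytes and PBMC of patients with JIA in remission and of healthy controls. The samples formed 6 groups: 13 healthy, 10 MTX and 12 MTX+Et samples of granulocytes, and 15 healthy, 14 MTX and 14 MTX+Et samples of PBMC. The comparisons asked how blood cells of patients in treated remission differed from those of healthy controls, and whether the 2 regimens differed. Values are log2 signals, and differences are log2 changes fitted with the array code letter (E, F or H) as a covariate. The SD of log2 signal over probe sets lay between 2.12 and 2.25 on every granulocyte array and between 2.16 and 2.26 on every PBMC array except 1. That array, an F array of the MTX+Et group, had an SD of 1.62 and a median correlation of 0.535 with the other PBMC arrays, of which the next lowest stood at 0.945. It is called the narrow-range array, and the main PBMC results are given with and without it. No H array came from a healthy sample, so differences of patients from healthy rest on the E and F arrays. H arrays enter them only through the difference between the regimens and through the spread. Counts of patient samples above or below the healthy mean hold H arrays as that fit places them. They are no separate check of single samples. In PBMC, MTX held 3 E and 2 F arrays and MTX+Et 1 E and 2 F arrays. In granulocytes, MTX held 5 E and 1 F array and MTX+Et 3 E and 1 F array.

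Marker genes separated the fractions as labelled. In healthy samples, 22 of 22 mature neutrophil markers were higher in granulocytes, with a median difference of 5.1 log2 units, while 20 of 20 T cell markers were lower, with a median of −3.28. Monocyte markers had a median of −2.37, B cell markers of −2.60 and cytotoxic lymphocyte and NK (natural killer) cell markers of −3.18. All 35 granulocyte arrays lay above every PBMC array in the mean of the neutrophil markers. Of the 43 PBMC arrays, 42 lay above every granulocyte array in the mean of the T cell markers.

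Granulocytes of patients on MTX alone differed from healthy granulocytes in 2 genes. KYAT3, which encodes a kynurenine aminotransferase of tryptophan breakdown, fell by 0.84 log2 units (SE 0.15, limma adjusted p = 0.0112, below the healthy mean in 10 of 10 samples). RSPRY1, a gene with RING finger and SPRY domains, fell by 0.43 (SE 0.07, adjusted p = 0.0112, also lower in 10 of 10). Over 15 alternatives KYAT3 passed in 9 and RSPRY1 in 7. Chance cannot be excluded for a count of 2 genes, as other splits of the samples reached it. Among E arrays the differences were −1.04 for KYAT3 and −0.53 for RSPRY1 (5 MTX and 6 healthy arrays), while F held 1 MTX array, too few, and H no healthy array. The next genes did not pass: HIGD1A, a mitochondrial protein induced in hypoxia, stood at −0.52, the nuclear receptor coactivator NCOA1 at −0.39 and UBN1, part of a histone chaperone complex, at 0.81, with adjusted p = 0.0644, 0.0923 and 0.154.

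No inflammatory or drug-handling list was called in this comparison in the reported fit. The type I interferon response list had a median of −0.35, with 4 of 30 genes higher and adjusted p = 0.0749 in camera, and the TNF and NF-kB target list a median of −0.14 (3 of 25 higher, adjusted p = 0.0749). Without 1 MTX H array, which stood far above the other 9 samples of its group in the interferon list, that list was called at −0.53 (adjusted p = 0.000183). Leaving out 1 MTX E, 2 MTX+Et E, 2 MTX+Et H, 3 healthy E or 1 healthy F array, each singly, also led to its call. The TNF targets were called without 1 MTX H, 1 MTX+Et E, 1 healthy E or 1 healthy F array, with a lowest adjusted p of 0.0163 at −0.15. With all arrays both lists were also called under 2 other settings. The replicate block gave −0.45 and −0.22 (each adjusted p = 0.00243, and adjusted p = 0.995 with an estimated correlation). With no filter on dim genes they stood at −0.35 and −0.11 (adjusted p = 0.0204 and 0.0423, and each adjusted p = 0.966 with an estimated correlation). They stood at 0.01 and −0.07 without the letter term, neither called. Folate cycle and methotrexate handling genes had a median of 0.02 (11 of 18 higher, adjusted p = 0.837). FPGS, which adds the glutamates that retain methotrexate in cells, stood at 0.16 (adjusted p = 0.695), the folate carrier SLC19A1 at 0.00 and TNF at 0.47 (SE 0.25, adjusted p = 0.655). T cell markers had a median of 0.24 (15 of 18 higher) and basophil and mast cell markers of 0.30 (8 of 10 higher), each with adjusted p = 0.0195, and with adjusted p = 0.981 with an estimated correlation. None of their members rose over all genes, or when adjusted over the list alone, and among E arrays the list means differed the other way, by −0.27 for T cells and −0.36 for basophils. Neither call held without the MTX F array, where both medians were 0.06 with adjusted p = 0.718, or without 1 MTX+Et F or 1 healthy F array. That of the T cell list also ended without 1 MTX E, 1 MTX+Et H, 1 healthy E or a further healthy F array. Of 11844 genes, 962 had an unadjusted p under 0.05. Without the letter term limma called 0 genes, with 572 at an unadjusted p under 0.05, KYAT3 at −0.47 and RSPRY1 at −0.32, and without the F array of the MTX group it called 21; leaving out 1 healthy F, 1 MTX+Et E or 1 MTX+Et H array gave 4 to 5.

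Granulocytes of patients on MTX+Et differed from healthy granulocytes in 79 genes, of which 11 rose and 68 fell. CD3G, a chain of the T cell receptor complex, rose by 1.78 (SE 0.36, limma adjusted p = 0.0194, higher in 12 of 12 samples). Among the other rises were QSER1 (1.09), SRM, which makes spermidine (0.66), TRAK2, an adaptor for mitochondrial transport (0.72), MCCC2 of leucine breakdown (0.81), the iron transporter SLC11A2 (0.52) and COX10 of heme A synthesis (0.37). Their adjusted p ran from 0.0227 to 0.0350, and each was higher in 11 or 12 of 12 samples. The falls were led by the centriole gene SCLT1 (−1.03, SE 0.23), the linker histone H1-2 (−0.97, SE 0.22), the ephrin receptor EPHB1 (−0.97) and FAR2, a fatty acyl reductase (−0.95). JADE1 of a histone acetylase complex fell by 0.89, the Notch inhibitor NUMB by 0.80 (SE 0.14, adjusted p = 0.0107) and TBXAS1, which makes thromboxane A, by 0.69 (SE 0.15, adjusted p = 0.0225), each lower in 12 of 12 samples. KYAT3 fell here too, by 0.69 (SE 0.16, adjusted p = 0.0288).

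Markers of mononuclear cells had higher medians in these granulocyte samples as whole lists, called by camera with its preset correlation only. T cell markers had a median of 0.91, with 18 of 18 genes higher, 1 that rose over all genes and 7 when adjusted over the list alone (camera adjusted p = 1.11e-10, and adjusted p = 0.523 with an estimated correlation). B cell markers had a median of 0.52 (20 of 20 higher, adjusted p = 1.75e-05), monocyte markers of 0.33 (16 of 20, adjusted p = 0.00440), cytotoxic and NK markers of 0.29 (23 of 27, adjusted p = 0.00428) and HLA class II genes of 0.46 (9 of 12, adjusted p = 0.0446). With an estimated correlation, monocyte markers had adjusted p = 0.523 and the other 3 lists adjusted p = 0.692. None of the members of these 4 lists rose, over all genes or adjusted over the list alone. Ribosomal protein genes had a median of 0.49 (35 of 35 higher, adjusted p = 1.87e-09, and adjusted p = 0.692 with an estimated correlation). Folate cycle and methotrexate handling genes had a median of 0.31, with 12 of 18 higher and 2 that rose and 1 that fell when adjusted over the list alone (adjusted p = 0.0180, and adjusted p = 0.523 with an estimated correlation). In healthy samples these 2 lists, like the mononuclear markers, were lower in granulocytes than in PBMC, with a median of −2.23 for folate genes (16 of 21 lower, 3 higher) and of −1.99 for ribosomal protein genes (35 of 35 lower). In the same samples FPGS stood at 0.32 (SE 0.10, adjusted p = 0.105) and SLC19A1 at −0.18. Among E arrays (3 MTX+Et and 6 healthy), list means differed by 0.65 for T cells, 0.40 for B cells, 0.21 for monocytes, 0.22 for cytotoxic and NK cells, 0.42 for HLA class II, 0.21 for ribosomal proteins and 0.25 for folate genes. The cytotoxic call ended without 1 MTX+Et E array (median 0.07, adjusted p = 0.180). The HLA class II call ended without any of 14 arrays (2 MTX E, 1 MTX F, 1 MTX H, 1 MTX+Et E, 1 MTX+Et F, 2 MTX+Et H, 2 healthy E and 4 healthy F), with adjusted p up to 0.292. The other 5 lists were called without each of the 35 arrays.

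TNF, the target of etanercept, stood at 0.85 in this comparison (SE 0.27, adjusted p = 0.108, higher in 11 of 12 samples) and its receptor TNFRSF1A at −0.07 (adjusted p = 0.827). The TNF and NF-kB target list had a median of 0.02 and the interferon list one of 0.05 (each adjusted p = 0.393). Both were called without the letter term, at 0.16 (17 of 25 higher, adjusted p = 0.00413, and adjusted p = 0.633 with an estimated correlation) and 0.53 (30 of 30, adjusted p = 4.78e-06, and adjusted p = 0.689 with an estimated correlation). Among E arrays all 79 called genes had the same sign, with a median change of 0.71 in the called direction against 0.55 in the fit, while F held 1 MTX+Et array, too few. The 79 genes were called in a fit that rests largely on these same E arrays, so the shared sign is no separate check. Without the letter term 196 genes were called, 27 of them shared with the 79, and CD3G stood at 0.54 and no longer passed. Single arrays moved the count: leaving out 1 of the 3 MTX+Et E arrays gave 1 to 176 genes, any of 5 healthy E arrays 26 to 52, either of 2 healthy F arrays 120 to 134, the MTX F array 177 and either of 2 MTX H arrays 49 to 177. Each of the 16 genes called and named in this comparison, CD3G among them, ended without at least 1 array, most often a MTX+Et E or a healthy E array, and none changed sign. Of the 16, 6 passed without the letter term, 6 with the replicate block, 6 with quantile normalization and 4 with the T cell list as covariate. With no filter on dim genes 15 passed, and with trend and robust options 16.

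**Figure D1:**
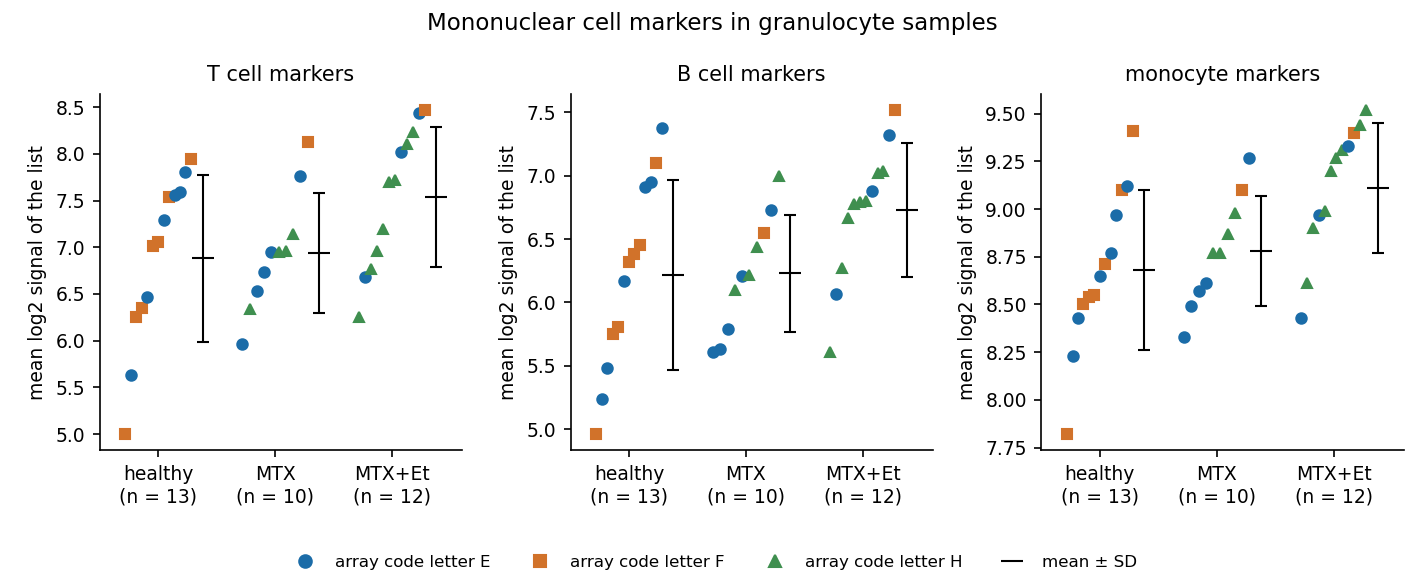
Each point is the mean log2 signal of 1 marker list on 1 granulocyte array, by group, with the array code letter shown by color and shape; bars are the group mean and SD. The mean of the T cell list was 6.88 ± 0.89 in healthy (n = 13), 6.94 ± 0.64 in MTX (n = 10) and 7.54 ± 0.75 in MTX+Et samples (n = 12), without adjustment for the letter.

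Between the regimens, no single gene passed in granulocytes, while the T cell list was higher with MTX+Et in camera with its preset correlation, though not with an estimated correlation (adjusted p = 0.407). The chloride channel gene CLIC4 stood at 1.11 (SE 0.29), the DNA repair gene NBN at 0.81, TRAF3, an adaptor of TNF receptor family signalling, at 0.65, H1-2 at −0.86 (SE 0.19), IGF1R at −0.66 and the kinase MAP3K3 at −0.41, each with limma adjusted p = 0.360. Among H arrays (8 MTX+Et and 4 MTX) the values were 0.37 for CLIC4, 0.29 for NBN, 0.37 for TRAF3, −0.43 for H1-2 and −0.27 for IGF1R. TNF stood at 0.38 (SE 0.23, adjusted p = 0.522) and FPGS at 0.16 (adjusted p = 0.482). T cell markers had a median of 0.76 (18 of 18 higher, camera adjusted p = 6.29e-09), B cell markers of 0.46 (20 of 20, adjusted p = 7.50e-07), cytotoxic and NK markers of 0.49 (24 of 27, adjusted p = 7.50e-07) and monocyte markers of 0.25 (16 of 20, adjusted p = 0.00423), each with adjusted p = 0.407 with an estimated correlation. Adjusted over the list alone, 1 T cell, 1 cytotoxic and 1 monocyte marker and 0 B cell markers rose.

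Inflammatory lists were also called in the same comparison with the preset correlation, though not with an estimated correlation. TNF and NF-kB targets had a median of 0.24, with 18 of 25 higher and 3 that rose when adjusted over the list alone (adjusted p = 0.000689, and adjusted p = 0.407 with an estimated correlation). Type I interferon response genes had a median of 0.38 (28 of 30 higher, adjusted p = 0.000883, and adjusted p = 0.668 with an estimated correlation), while mature neutrophil markers had a median of −0.19 (4 of 22 higher, adjusted p = 0.00423, and adjusted p = 0.525 with an estimated correlation). In the interferon list 1 MTX H array stood far above its group. Without it the median was 0.78 (adjusted p = 1.89e-12), and without another MTX H array 0.18, no longer called (adjusted p = 0.0724). In the neutrophil list the MTX F array stood apart, and without it the median was −0.20 (adjusted p = 0.00287). Under E (3 MTX+Et and 5 MTX arrays) and H, the T cell list differed by 0.92 and 0.51, the B cell list by 0.76 and 0.18, the monocyte list by 0.25 and 0.31, the cytotoxic list by 0.77 and 0.31, the interferon list by 1.04 and 0.29 and the TNF target list by 0.36 and 0.07. For mature neutrophil markers the sign differed, at −0.26 and 0.04, and F held 1 array of each regimen, too few. limma called 0 genes in this comparison, with 1307 at an unadjusted p under 0.05.

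PBMC of patients on MTX alone had lower levels of genes of cytotoxic lymphocytes than healthy PBMC. Granzyme K (GZMK) fell by 1.01 (SE 0.22, limma adjusted p = 0.0179, lower in 14 of 14 samples), granzyme A (GZMA) by 1.09 (SE 0.27), the NK receptor genes KLRC3 and KLRD1 by 1.25 and 1.0, and EOMES, a transcription factor of effector lymphocytes, by 0.81. All 5 passed again when the narrow-range array was left out, at −0.91 for GZMK, −0.82 for GZMA, −1.13 for KLRC3, −0.87 for KLRD1 and −0.67 for EOMES. PDK4, a kinase that restrains pyruvate oxidation, fell by 1.36 (SE 0.34, adjusted p = 0.0317) and PRDM1, a regulator of effector lymphocytes and plasma cells, by 1.06. The largest rises were in COL18A1, a collagen gene (1.0, SE 0.26), the scaffold gene STRN4 (0.84), the calcium-activated potassium channel gene KCNN4 (0.83, SE 0.14, adjusted p = 0.00396, higher in 14 of 14 samples) and UAP1L1 (0.74). These 6 genes passed as well without the narrow-range array, at −1.28 for PDK4, −1.0 for PRDM1, 1.03 for COL18A1, 0.79 for STRN4, 0.87 for KCNN4 and 0.76 for UAP1L1. The narrow-range array belongs to neither group compared here. As an F array it still enters the letter term that all groups share, so the fitted changes moved when it was left out. The median change over all genes was −0.08 with it and −0.01 without. GZMA went from −1.09 to −0.82 and KCNN4 from 0.83 to 0.87. Leaving it out also narrowed the spread that all groups share (mean SE 0.15 with it, 0.11 without), so passing again is a weak check. These 11 calls depended on the model and on single arrays. None of the 11 genes passed without the letter term, with E and F arrays only or with F arrays only, the last 2 with fewer samples. With the replicate block 5 passed, without the letter and the narrow-range array 3, and with E arrays alone 10. KCNN4 was the only one that passed without each array in turn. Once the narrow-range array was out, COL18A1, STRN4, KCNN4, UAP1L1 and GZMK passed without each further array. PDK4, KLRC3, GZMA, EOMES and PRDM1 then ended without 1 or 2 MTX E arrays singly, and KLRD1 without 2 MTX E, 1 MTX+Et F or 1 healthy E array.

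In all, 133 genes rose and 127 fell in this comparison, and 831 rose and 402 fell without the narrow-range array, among them all 260. The cytotoxic lymphocyte and NK list had a median of −0.76, with 0 of 27 genes higher, 5 that fell over all genes and 17 when adjusted over the list alone (camera adjusted p = 1.38e-06, and adjusted p = 0.968 with an estimated correlation). Its median was −0.53 without the narrow-range array (3 of 27 higher, 5 fell, 8 adjusted over the list alone, adjusted p = 1.57e-05, and adjusted p = 0.998 with an estimated correlation). Type I interferon response genes had a median of −0.39, with 1 of 30 higher and none past the threshold (adjusted p = 0.0152, and adjusted p = 0.968 with an estimated correlation), and of −0.22 without that array (adjusted p = 0.0302, and adjusted p = 0.998 with an estimated correlation). The interferon call ended without the other MTX+Et F array (−0.35, adjusted p = 0.120) or 1 healthy F array. Once the narrow-range array was out it ended without either MTX F array, the MTX+Et F array, 2 healthy E or 2 healthy F arrays singly (adjusted p up to 0.245). TNF and NF-kB targets had a median of −0.06 (adjusted p = 0.820), T cell markers of −0.27 (3 of 20 higher, adjusted p = 0.260) and folate genes of −0.07 (adjusted p = 0.820), and without the narrow-range array the medians were 0.13, −0.02 and 0.02. TNF stood at 0.44 (SE 0.27, adjusted p = 0.295), TNFRSF1A at 0.09, FPGS at 0.03, SLC19A1 at −0.01 and TYMS, which makes thymidylate, at −0.19 (adjusted p = 0.784), and without that array at 0.49, 0.24, 0.08, 0.05 and −0.23.

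Under the letters, the 260 genes differed by a median of 0.62 in the called direction among E arrays (3 MTX and 7 healthy; 260 of the same sign) and of 0.12 among F arrays (2 MTX and 8 healthy; 231 of the same sign), against 0.40 in the fit. The 260 genes were called in a fit that rests on these same arrays, so shared signs are no separate check. The cytotoxic list mean differed by −0.54 under E and by −0.22 under F, and the interferon list mean by −0.11 and −0.35. Among the lists that changed sign, mature neutrophil markers differed by 1.03 and −0.63, and immediate early and handling genes by −0.66 and 0.16. GZMK stood at −1.23 and −0.64, GZMA at −0.87 and −0.59, PDK4 at −1.31 and −1.99, KCNN4 at 1.07 and 0.58, and STRN4 at 1.32 and 0.18. Without the letter term limma called 1 gene, and without the letter and the narrow-range array 47, of which 13 were shared with the 260; 2741 genes had an unadjusted p under 0.05 with all arrays. Leaving out 1 of the 3 MTX E arrays gave 3 to 60 genes, 1 of 2 MTX F arrays 614 to 1130, 1 of 2 MTX+Et F arrays 765 to 1233 (the higher without the narrow-range array), any of 6 healthy E arrays 101 to 169, and a healthy F, MTX+Et E or MTX+Et H array 168, 94 or 171. Quantile normalization moved the rises and falls to 483 and 120, and centring each array on its median to 420 and 273. After the narrow-range array had been left out, leaving out a further MTX E array gave 371 to 674, a MTX F array 2106 and the MTX+Et E array 768.

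PBMC of patients on MTX+Et had higher levels of the complement gene C3 than healthy PBMC, and TNF, a dim gene on these arrays, passed with a smaller margin. C3 rose by 1.11 (SE 0.19, limma adjusted p = 0.00270) and TNF by 0.88 (SE 0.29, adjusted p = 0.0399). Both were higher in 14 of 14 samples after the letter term was removed, where the fit itself places the 11 H arrays. Without that step the lowest C3 value with MTX+Et was 6.32, below the healthy mean of 6.47. TNF averaged 5.27 in healthy PBMC and 6.05 with MTX+Et, near the lowest mean of the genes kept (5.18) and the mean array median of healthy PBMC (5.14), so the size of its rise is uncertain. Without the narrow-range array C3 stood at 0.92 (adjusted p = 0.00454) and TNF at 0.97 (adjusted p = 0.0484). With all arrays C3 passed without each array in turn, while TNF ended without 1 MTX E, 1 MTX+Et E, 2 healthy E or 1 healthy F array singly (adjusted p up to 0.0574). Once the narrow-range array was out, C3 no longer passed without the MTX+Et E array, at 0.77 (adjusted p = 0.0647), and TNF without any of 28 further arrays of every group (adjusted p up to 0.156). Over 15 alternatives C3 passed in 12 (adjusted p from 3.18e-05 to 0.116) and TNF in 9 (adjusted p from 0.0141 to 0.509). UAP1L1 rose by 0.85, STRN4 by 0.78, KCNN4 by 0.74 (SE 0.15, adjusted p = 0.0118), CD101, a membrane protein of myeloid and T cells, by 0.70, and RELB, an NF-kB subunit, by 0.43 (SE 0.14, adjusted p = 0.0375, higher in 12 of 14). Each of these passed without the narrow-range array, at 0.89 for UAP1L1, 0.68 for STRN4, 0.81 for KCNN4, 0.78 for CD101 and 0.54 for RELB. In that setting all but KCNN4 no longer passed once the MTX+Et E array was left out too (adjusted p from 0.0528 for UAP1L1 to 0.145 for CD101), and STRN4 also ended without 2 MTX E arrays singly. PDK4 fell by 1.61 (SE 0.37, adjusted p = 0.0189, lower in 14 of 14), KLRC3 by 1.37 and the steroid-reducing enzyme gene AKR1C3 by 1.32, and they passed again at −1.46, −1.14 and −1.37, where AKR1C3 and KLRC3 were named only after that array had been left out. These 3 calls then ended without 1 further array: PDK4 without 1 MTX E (adjusted p = 0.0527), KLRC3 without 2 MTX E or the MTX+Et E array (up to 0.108), and AKR1C3 without 1 MTX E or the MTX+Et E array (up to 0.185). Of the 16 genes called and named in this comparison, 8 passed without each array in turn. Of the 14 called without the narrow-range array, 2 passed without each further array (KCNN4 and NFKB2) and 12 did not. None of the 16 passed without the letter term or with F arrays alone, 3 passed with the replicate block and 13 with E and F arrays.

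Most of the largest falls no longer passed without the narrow-range array. With all arrays 312 genes rose and 1464 fell, and without it 669 rose and 174 fell, with 334 shared. Of the 12 largest falls 2 passed without it. CXCR4, a chemokine receptor, went from −1.72 to −0.60, SRGN, the granule proteoglycan serglycin, from −1.66 to −0.40, and the ribosomal protein gene RPL24 from −1.45 to −0.13. Of these 3, SRGN alone still passed, and its call ended when any 1 of 14 further arrays was left out. The median over all genes was −0.13 with all arrays, and the changes are to be read against it. Quantile normalization of all arrays gave 1415 rises and 1002 falls, and centring on the median 1173 and 1351.

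Cytotoxic genes were lower here as well. The cytotoxic lymphocyte and NK list had a median of −0.78, with 0 of 27 higher, 10 that fell over all genes and 16 when adjusted over the list alone (camera adjusted p = 0.00286, and adjusted p = 0.964 with an estimated correlation). Its median without the narrow-range array was −0.31, with 4 of 27 higher and 0 that fell, over all genes or adjusted over the list alone (adjusted p = 0.0202, and adjusted p = 0.973 with an estimated correlation). Leaving out the other MTX+Et F array ended the call with all arrays (−0.85, adjusted p = 0.0592). The call without the narrow-range array ended without the MTX+Et F array (−0.13, adjusted p = 0.413), 1 MTX E or 1 MTX F array. GZMB fell by 1.14, KLRF1 by 1.30 and GZMA by 0.99 with all arrays. They stood at −0.81, −1.14 and −0.49 without it and did not pass. TNF and NF-kB targets had a median of −0.06 with a test pointing up (1 rose, 2 fell, adjusted p = 0.244). Once the narrow-range array was left out, their median was 0.20, with 16 of 23 higher and 7 that rose, also when adjusted over the list alone (adjusted p = 0.0229, and adjusted p = 0.973 with an estimated correlation). This call ended without the remaining MTX+Et F array (0.16, adjusted p = 0.242), 1 MTX+Et H or 1 MTX F array. The NF-kB subunit NFKB2 then stood at 0.78 and the adhesion gene ICAM1 at 0.68, both passing, against 0.42 and 0.43 with all arrays, where neither did; both were named after the data were seen. NFKB2 passed without each further array (adjusted p up to 0.00961), while ICAM1 ended without the MTX+Et E array (adjusted p = 0.0997). B cell markers had a median of 0.13 (15 of 22 higher, 0 rose, adjusted p = 0.00943, and adjusted p = 0.964 with an estimated correlation), and of 0.23 without that array (18 of 22 higher, 2 rose, adjusted p = 0.0358, and adjusted p = 0.973 with an estimated correlation), with CD79A of the B cell receptor at 1.03 against 0.39. The CD79A call also ended without the MTX+Et E array (adjusted p = 0.0997). The B cell call ended without the MTX+Et E array (0.03, adjusted p = 0.146) or the other MTX+Et F array. With the narrow-range array out it ended without any of 15 arrays (1 MTX F, 5 MTX H, 1 MTX+Et E, 1 MTX+Et F, 2 MTX+Et H, 3 healthy E and 2 healthy F; adjusted p up to 0.443). T cell markers had a median of −0.48 (adjusted p = 0.0739) and of −0.03 without it. TNFRSF1A stood at −0.11, TNFRSF1B at −0.33, FPGS at 0.06, TYMS at −0.11 and SLC19A1 at −0.12, with adjusted p from 0.192 to 0.877. Their values without the narrow-range array were 0.18, 0.07, 0.15, −0.18 and −0.01, and centring each array turned TNFRSF1A, TYMS and SLC19A1 to 0.05, 0.05 and 0.04.

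Under F (2 MTX+Et arrays, the narrow-range array included, and 8 healthy arrays) the 1776 genes differed by a median of 0.98 in the called direction, with 1732 of the same sign, against 0.54 in the fit. The 1776 genes were called in a fit that holds these same F arrays, so the shared sign is no separate check. E held 1 MTX+Et array, and F held 1 without the narrow-range array, too few for a value. Without the letter term limma called 9 genes, and C3 stood at 0.67 and TNF at 0.78, neither passing. Without the letter and the narrow-range array 295 genes were called, 51 of them shared with the 1776, and 4298 genes had an unadjusted p under 0.05 with all arrays. Leaving out the other MTX+Et F array gave 3440 genes, 1 of 2 MTX F arrays 2713 to 2915, and 1 MTX E, 1 healthy E or 1 healthy F array 682, 1173 or 1077. Once the narrow-range array was out, leaving out the MTX+Et E array as well gave 23 genes, 1 of 3 MTX E arrays 375 to 497 and 1 MTX F array 1438.

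**Figure D2:**
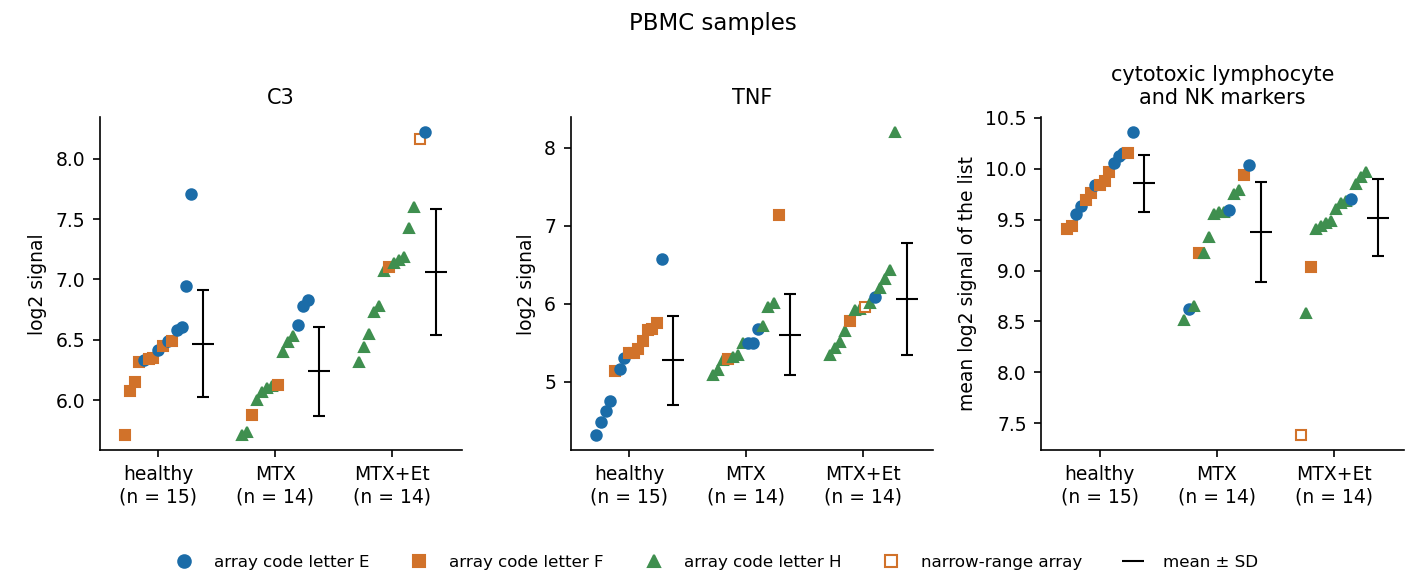
Each point is 1 PBMC array, by group, with the log2 signal of C3, the log2 signal of TNF and the mean log2 signal of the cytotoxic lymphocyte and NK list; color and shape give the array code letter and the open square is the narrow-range array. Bars are the mean and SD without that array, which for C3 were 6.47 ± 0.44 in healthy (n = 15), 6.24 ± 0.37 in MTX (n = 14) and 7.06 ± 0.52 in MTX+Et samples (n = 13), without adjustment for the letter.

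Between the regimens, C3 was the single gene that passed in PBMC. C3, the central component of the complement cascade, was higher with MTX+Et than with MTX by 1.01 (SE 0.14, limma adjusted p = 0.000170, higher in 14 of 14 samples), and by 0.92 without the narrow-range array (adjusted p = 0.000444). It differed by 1.62 among F arrays (2 and 2, with the narrow-range array) and by 0.82 among H arrays (11 MTX+Et and 9 MTX), while E held 1 MTX+Et array, too few. Without the letter term it stood at 0.89 (adjusted p = 0.0666), and among H arrays alone it did not pass; over 15 alternatives it ranged from 0.81 to 1.11, with adjusted p from 1.90e-07 to 0.297, and passed in 12. Values for the genes next in order, which did not pass, were 0.28 for the glutathione transferase GSTA4, 0.25 for the metallothionein MT1F, −0.44 for IGF1R and −0.40 for the lysosomal enzyme gene GLA, each with adjusted p = 0.693 and of the same sign without the narrow-range array. TNF stood at 0.44 (SE 0.22, adjusted p = 0.693) and FPGS at 0.03.

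B cell, interferon and platelet lists differed between the regimens in PBMC. B cell markers had a median of 0.22 (18 of 22 higher, camera adjusted p = 6.78e-11, and adjusted p = 0.938 with an estimated correlation), and of 0.29 without the narrow-range array (21 of 22 higher). Type I interferon response genes had a median of 0.13 (24 of 30, adjusted p = 5.58e-07, and adjusted p = 0.938 with an estimated correlation), and of 0.25 without that array (30 of 30). Platelet markers had a median of −0.45 (0 of 21, adjusted p = 7.39e-07, and adjusted p = 0.938 with an estimated correlation), and of −0.33 without it (0 of 21). TNF and NF-kB targets had a median of 0.06 (12 of 23, adjusted p = 0.00177, and adjusted p = 0.938 with an estimated correlation), and of 0.12 without it (19 of 23). The cytotoxic list had a median of −0.04 while its test pointed up (adjusted p = 0.0469, and adjusted p = 0.938 with an estimated correlation), and a median of 0.17 without it (23 of 27 higher). No member of these 5 lists passed with all arrays, over all genes or adjusted over the list alone. Among H arrays the list means differed by 0.15 for B cells, 0.29 for interferon genes, −0.37 for platelets, 0.14 for TNF targets and 0.23 for cytotoxic cells. The first 4 lists were called without each array in turn. The cytotoxic call ended without any of 17 arrays (1 MTX E, 1 MTX F, 3 MTX H, 1 MTX+Et E, 7 MTX+Et H, 2 healthy E and 2 healthy F; adjusted p up to 0.716). With the narrow-range array out, it ended without 1 MTX H array (0.07, adjusted p = 0.147). The reported fit with all arrays did not call interferon gamma response genes, but the fit without that array did, at 0.15 (21 of 22 higher, adjusted p = 1.41e-05, and adjusted p = 0.398 with an estimated correlation). The same holds for mature neutrophil markers, at −0.19 (2 of 19 higher, adjusted p = 4.79e-05, and adjusted p = 0.460 with an estimated correlation). In this comparison 447 genes had an unadjusted p under 0.05.

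**Figure D3:**
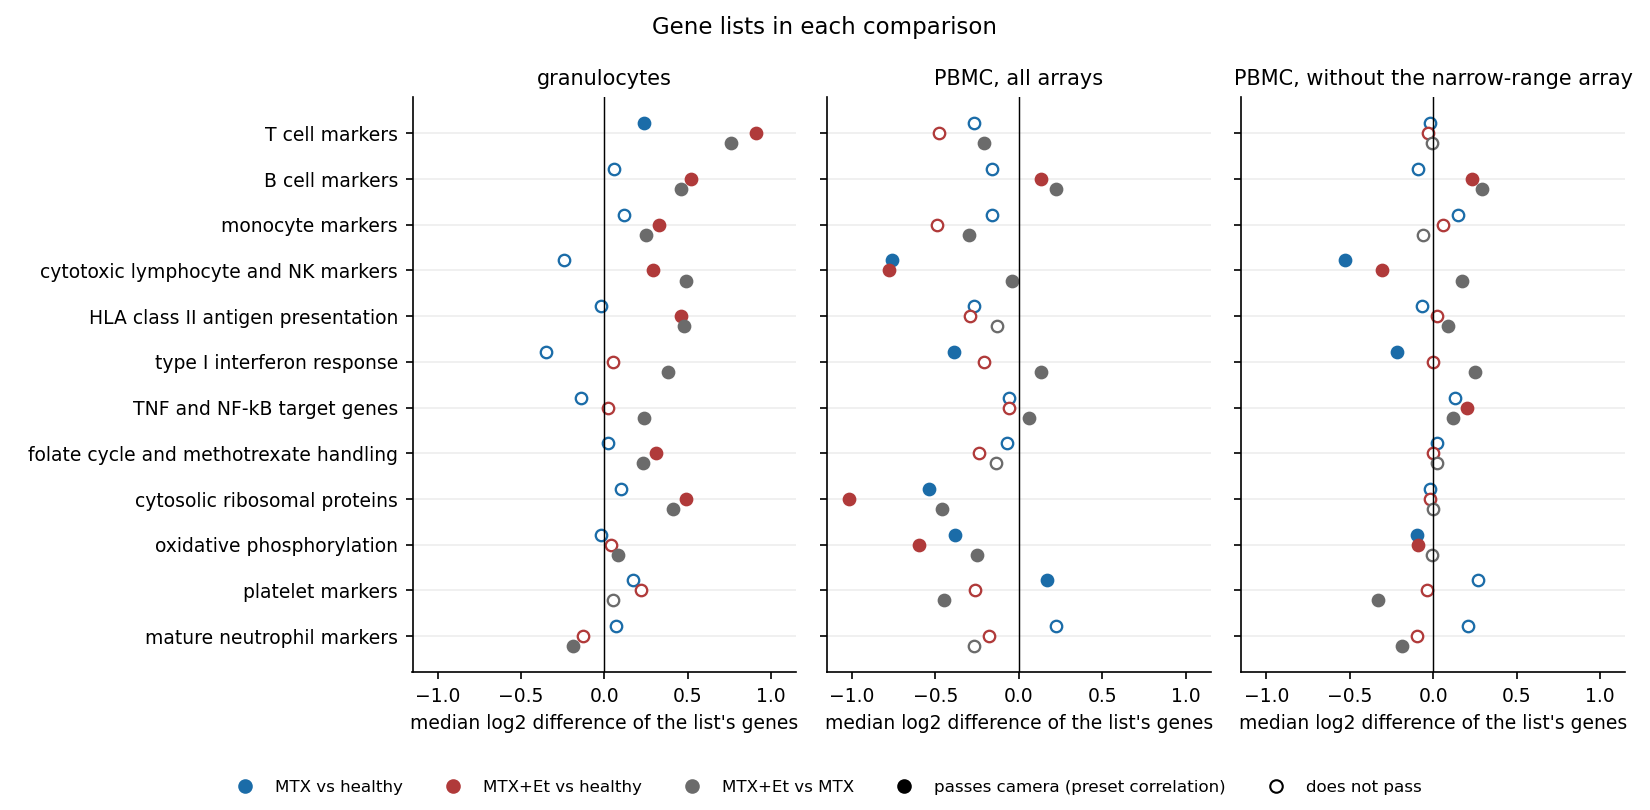
Each point is the median log2 difference over the genes of 1 list in 1 comparison, in granulocytes, in PBMC and in PBMC without the narrow-range array; filled points passed camera with its preset correlation and none passed with an estimated correlation. T cell markers stand at 0.91 in MTX+Et against healthy granulocytes, and cytotoxic lymphocyte and NK markers at −0.76 and −0.78 in PBMC of the regimens against healthy.

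Both regimens shared calls against the same healthy samples. In PBMC 226 genes were called in the same direction in both comparisons with healthy, 111 up and 115 down, against 3.50 and 15.7 for independent lists. Simulated unchanged groups that share the healthy samples gave a median of 0 shared calls and at most 1. The draws shuffled what the fit left over among all arrays of a cell type. A difference particular to 1 letter within a group is lost in them, so they cannot exclude it as a source of shared calls. The correlation of changes across genes, which are not independent replicates, was 0.90 and lay inside the simulated range of 0.08 to 0.93 (median 0.68). The covariance was 0.0713 against a simulated mean of 0.0181 (SD 0.0121). With the narrow-range array left out 691 genes were shared, the correlation of 0.89 lay above the simulated 0.38 to 0.84, and the covariance was 0.0395 against 0.0132 (SD 0.00431). When each regimen was set against its own part of the healthy samples, the median over 20 splits was 0 shared calls in PBMC and in granulocytes, and the correlation was 0.23 in PBMC and 0.50 (0.40 to 0.58) without the narrow-range array. Each regimen then had fewer healthy samples, so a count of 0 may reflect less power. In granulocytes 2 genes were shared, KYAT3 and RSPRY1, both down, and the correlation of 0.59 was below the simulated 0.62.

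The difference between MTX+Et and healthy samples was not the same in both cell types for 20 genes by the interaction test, in which patient, disease and treatment are not separated, 7 with a higher and 13 with a lower value in PBMC. The C3 difference was higher in PBMC by 1.01 (SE 0.24, limma adjusted p = 0.0418), at 1.11 against 0.11 in granulocytes. CD3G differed by −2.17 (SE 0.41, adjusted p = 0.00447), TRAK2 by −1.07 (SE 0.20, adjusted p = 0.00447), PRDM1 by −1.65 (SE 0.39, adjusted p = 0.0447) and RXYLT1, a sugar transferase gene, by −0.77 (SE 0.18, adjusted p = 0.0418). Without the narrow-range array 166 genes differed, 154 higher and 12 lower in PBMC, with C3 at 0.82, CD3G at −1.88, TRAK2 at −0.89, PRDM1 at −1.53 and RXYLT1 at −0.66, all of which passed. For MTX against healthy, and for MTX+Et against MTX, limma called 0 genes in this test, with 442 and 1176 at an unadjusted p under 0.05.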

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

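The tests of the narrow-range array, those with single arrays left out and that with the 3' minus 5' difference as a covariate were chosen after the result was seen; those of the letters and of the correlations of mononuclear markers were set down before their results were seen.

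Single far samples were looked for in groups of 4 to 10 samples, and the granulocyte MTX group (10 samples) was the only such group. Of 77 values tested there, 7 had a sample far from the others, where chance gives about 5 percent for like samples. The values were not adjusted for the letter, and the group held 5 E, 1 F and 4 H arrays, so the letter can set a sample apart. The 77 values come from the same arrays and are not independent. The gap to the nearest sample, as a share of the group's range, was 0.625 for the type I interferon response list, 0.473 for mature neutrophil markers, 0.627 for glucocorticoid responsive genes and 0.522 for HLA class II genes. It was 0.50 for LOC100506639, 0.489 for RXYLT1 and 0.510 for SLC11A2. Without the sample farthest from its group, the interferon list went from −0.35 to −0.53 for MTX against healthy, and was then called, and from 0.38 to 0.78 between the regimens. The glucocorticoid list went from −0.19 to −0.10 between the regimens and was no longer called (adjusted p = 0.144). The neutrophil and HLA class II lists stayed called there, at −0.20 and 0.38.

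The difference of MTX+Et against healthy was not the same in PBMC and granulocytes for 20 genes by the interaction test. Counting the real one, 3 of 100 splits over all samples reached that number, and the highest other gave 326. Within letters the real split alone reached it, with a highest other of 11. Such tests were not adjusted for their number, so chance is not excluded, and what lies behind the 326 was not tested. The named genes among the 20 were TRAK2 (−1.07), CD3G (−2.17), RXYLT1 (−0.77), C3 (1.01) and PRDM1 (−1.65), as PBMC minus granulocyte differences. Probe sets without a single gene symbol, which no comparison of genes used, also held calls: 5 of 5020 for MTX and 51 for MTX+Et against healthy in granulocytes, and 358 of 5008 and 571 in PBMC. Without the narrow-range array the PBMC counts were 517 and 146.

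The 1 MTX+Et PBMC array with a narrow range of values had a 3' minus 5' difference of 4.68 log2 units at the ACTB control probe sets, against 0.07 to 0.88 on the other PBMC arrays, and of 1.17 at GAPDH, against −0.24 to 0.41. These values are consistent with degraded or 3'-biased RNA on that array. The T cell list mean of that array lay within the range of granulocyte arrays, but a narrowed range lowers all bright markers, so the order of 2 lists within each array was compared. The T cell mean was above the neutrophil mean on that array, as on the other 42 PBMC arrays, and on 0 of the 35 granulocyte arrays. Its Spearman correlation was 0.82 with the healthy PBMC mean and 0.75 with the healthy granulocyte mean. These values argue against a granulocyte sample under a PBMC label. No biological explanation was tested, because the pattern is in a single array.

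Among E arrays alone, 2575 genes were called between MTX and healthy PBMC, from 3 and 7 arrays. Over these genes, the slope of the change among F arrays (2 and 8 arrays) on the change among E arrays was −0.02, and with each F array left out in turn at most 0.04, with 47.5 percent of genes of the same sign. The bound set beforehand for a difference between patients on MTX and healthy controls of like size under every letter was a slope of 0.5 or above. The values did not reach it. The genes were chosen by their change among E arrays, which by itself lowers the slope. F held 2 MTX arrays, and no E array was left out, so the slope cannot exclude such a difference. The values show only that the changes among E arrays were not seen again among these F arrays. Such values would also arise if E arrays of 1 of the groups differed from the rest for a reason other than health or treatment. Which group that is stays open, as does a difference between the patients whose arrays carry E and F. The cytotoxic list, GZMK, PDK4 and KCNN4 kept their sign under both letters, as given with that comparison. They were called in a fit that holds these same arrays, so the shared sign is no separate check.

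T cell, B cell and monocyte markers were higher in granulocyte samples of the MTX+Et group. Across the 35 granulocyte arrays, after group and letter were removed, the mean of the T cell list correlated with that of the B cell list (r = 0.89, rho = 0.87) and of the monocyte list (r = 0.78, rho = 0.73), each with a permutation p of 1.0e-05, the smallest that 100000 resamples can give, and 1.5e-05 adjusted over the 3 relations tested. Without the 2 farthest arrays r was 0.86 and 0.71, and within E, F and H arrays (14, 9 and 12) it was 0.89, 0.94 and 0.84 for B cells and 0.76, 0.91 and 0.59 for monocytes; this is consistent with a varying share of mononuclear cells in the granulocyte fraction, where T cell markers measured in both fractions averaged 6.89 in healthy samples against 10.01 in PBMC. Folate and ribosomal protein genes were also lower in granulocytes than in PBMC, so a larger share of mononuclear cells would raise them too. Neither list was called with an estimated correlation. Whether the higher medians of these lists with MTX+Et have that source was not tested and stays open. The T cell list also correlated with the 3' minus 5' difference at r = 0.40, between the bounds set for and against lower RNA quality. With the letter in the fit, that measure was lower in MTX+Et than in healthy samples, by 0.16 (SE 0.10), and with it as a covariate the T cell list difference went from 0.94 (SE 0.41) to 1.20 (SE 0.40). The difference in the measure did not clear its spread, and without the letter its means were 0.40 in healthy and 0.38 in MTX+Et samples. The T cell difference left with the covariate argues against RNA quality, so far as this measure holds it, as the cause of the rise over healthy. Against MTX the measure differed by 0.05 (SE 0.09) and the T cell difference went from 0.69 (SE 0.35) to 0.61 (SE 0.33). There RNA quality cannot be told apart from the others, since neither value clears its spread. With the T cell list as a covariate 37 genes were called between MTX+Et and healthy granulocytes, 21 of them among the 79. Of the 16 genes called and named in that comparison, 4 still passed and 12 did not. The covariate is a mean of T cell markers alone, so the calls left standing are not shown to be free of mononuclear cells. A difference in the blood of the patients stays untested.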

How the results depend on the processing

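The alternatives with F arrays alone, without the narrow-range array, with a 3' minus 5' or T cell covariate, and with each array left out were chosen after the data were seen, and the cause was not tested unless a sentence gives it. Of the counts of called genes, 60 stayed within 1.5 times the value of the report and 61 moved beyond it. Of the tests of called lists, 163 kept direction and side of the threshold, 106 kept the direction alone and 6 reversed. With each array left out in turn, 23 of the 47 list calls held every time (16 of 27 in granulocytes, 7 of 20 in PBMC) and 24 ended at least once. For named genes, 957 values kept both, 247 no longer passed, 30 passed in addition and 45 that passed under neither setting changed sign. The count for MTX+Et against MTX in granulocytes, 0 in the report by limma, was 11 with all 6 groups in 1 fit and 0 under every other alternative run, where, leaving aside the fits without 1 array, 288 (H arrays alone) to 2513 (all probe sets) had an unadjusted p under 0.05. Single-gene values under 1 letter are not given where a group held 1 array, and the counts there assume that the lone array varies like the other groups.

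For MTX against healthy granulocytes (2 genes), 0 genes were called without the letter, with quantile normalization, with centring, with only the 2 groups compared, with E and F arrays only, with F arrays only and with the 3' minus 5' covariate. In these limma fits 572, 931, 711, 1078, 981, 351 and 677 genes in turn had an unadjusted p under 0.05. Further counts were 5 with no filter on dim genes, 1 with the mean of a gene's probe sets, 14 with 6 groups in 1 fit, 1 at 1.5-fold or more, 39 among E arrays, 4 with the T cell list as covariate, and 2 to 21 when each array was left out. For MTX+Et against healthy granulocytes (79 genes) the counts were 196 without the letter, 45 with the mean of probe sets, 206 with all probe sets, 19 with quantile normalization, 43 with centring, 267 with 6 groups in 1 fit, 126 with only 2 groups, 32 at 1.5-fold, 161 among E arrays, 0 among F arrays (672 at an unadjusted p under 0.05), 37 with the T cell list as covariate and 1 to 177 when each array was left out. The fold threshold and the single letters leave fewer genes or fewer samples by construction.

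For MTX against healthy PBMC (260 genes) the counts were 1 without the letter, 169 with no filter, 158 with 60 percent left out, 598 with all probe sets, 603 with quantile normalization, 693 with centring, 1560 with array weights, 106 with 6 groups in 1 fit, 669 with only 2 groups, 49 at 1.5-fold, 0 with E and F arrays (1552 at an unadjusted p under 0.05), 2575 among E arrays, 0 among F arrays (176 unadjusted), 1233 without the narrow-range array, 47 without it and the letter, 1304 with the 3' minus 5' covariate and 3 to 1233 when each array was left out. For MTX+Et against healthy PBMC (1776 genes) they were 9 without the letter, 99 with the replicate number as a block, 3868 with only 2 groups, 775 at 1.5-fold, 223 among E arrays, 0 among F arrays (5285 unadjusted), 843 without the narrow-range array, 295 without it and the letter, 759 with the 3' minus 5' covariate and 682 to 3440 when each array was left out. For MTX+Et against MTX in PBMC (1 gene) 0 were called without the letter, without the letter and the narrow-range array, with 60 percent left out and among H arrays, with 250, 348, 280 and 224 at an unadjusted p under 0.05. With 60 percent left out C3 was itself filtered out and not tested.

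The replicate block gave 2, 76 and 0 genes in granulocytes and 278, 99 and 1 in PBMC for the 3 comparisons in turn. Numbers shared across groups did not pair samples: the mean correlation of samples with the same number was −0.04 in granulocytes (32 pairs) and −0.01 in PBMC (42 pairs). The interaction count for MTX+Et against healthy (20) was 490 with centring, 2 with the replicate block and 166 without the narrow-range array. Shared calls of both regimens were 0 in granulocytes without the letter and with split healthy samples, and in PBMC 1 without the letter, 691 without the narrow-range array and 0 with split healthy samples. With an estimated correlation 0 lists were called in either cell type, against 27 in granulocytes and 20 in PBMC, and with no filter 34 in PBMC. For MTX+Et against MTX in PBMC the T cell list (−0.21) reversed its test at a median of −0.01 without the narrow-range array and 0.02 without it and the letter, and the ribosomal list (−0.46) at 0.00 without that array. For MTX+Et against MTX in granulocytes the erythroid list (0.40) reversed its test at −0.05 without 1 MTX+Et E array. Dim genes sit near background on these arrays, so small changes in them are out of reach.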

Other observations

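The tests of other splits drawn within each letter, and those with single arrays or the narrow-range array left out, were chosen after the results were seen.

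Several gene groups outside the main comparisons were called in granulocytes by camera with its preset correlation, though not with an estimated correlation. Erythroid and reticulocyte markers had a median of 0.48 in MTX+Et against healthy samples (16 of 17 higher, camera adjusted p = 0.00440, and adjusted p = 0.692 with an estimated correlation) and of 0.40 against MTX (15 of 17, adjusted p = 0.0242, and adjusted p = 0.668 with an estimated correlation). Plasma cell markers had medians of 0.30 (10 of 11) and 0.18 (9 of 11), with adjusted p = 0.00209 and 0.00423, and with adjusted p = 0.283 and 0.407 with an estimated correlation. Basophil and mast cell markers had a median of 0.36 against healthy (8 of 10, adjusted p = 0.0173, and adjusted p = 0.692 with an estimated correlation). Against MTX, ribosomal protein genes had a median of 0.41 (35 of 35, adjusted p = 4.22e-09, and adjusted p = 0.525 with an estimated correlation), HLA class II genes of 0.48 (10 of 12, adjusted p = 0.00364, and adjusted p = 0.413 with an estimated correlation), folate genes of 0.23 (13 of 18, adjusted p = 0.00529, and adjusted p = 0.407 with an estimated correlation) and glucocorticoid responsive genes of −0.19 (5 of 19, adjusted p = 0.0184, and adjusted p = 0.407 with an estimated correlation). Interferon gamma response genes stood at 0.18 and oxidative phosphorylation genes at 0.08 there, with adjusted p = 0.0239 and 0.0339, and each with adjusted p = 0.668 with an estimated correlation. Between MTX+Et and MTX the erythroid list means differed by 1.57 under E and by −0.56 under H, and those of the interferon gamma list by 0.80 and −0.12. Both erythroid calls ended without 1 MTX+Et E array, at −0.01 against healthy (adjusted p = 0.810) and −0.05 against MTX (adjusted p = 0.761). The second also ended without 1 MTX E, 1 MTX F or 1 MTX+Et H array. The basophil call ended without the MTX F or the MTX+Et F array, and the glucocorticoid call without 1 MTX E (−0.10, adjusted p = 0.144) or 1 MTX+Et E array. Those of interferon gamma genes (2 MTX E, 1 MTX F, 1 MTX H, 2 MTX+Et E and 1 MTX+Et H array) and of oxidative phosphorylation (1 MTX E, 1 MTX H, 1 MTX+Et E, 1 MTX+Et F and 2 MTX+Et H arrays) ended without any of 7 and 6 arrays.

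In PBMC, oxidative phosphorylation genes, which make ATP in mitochondria, had a median of −0.38 with MTX against healthy (3 of 38 higher, adjusted p = 0.00101, and adjusted p = 0.968 with an estimated correlation) and of −0.60 with MTX+Et (1 of 38 higher, 18 fell, adjusted p = 6.97e-06, and adjusted p = 0.964 with an estimated correlation). Without the narrow-range array these medians were −0.10 and −0.09, with 0 that fell in either, and the list was still called (adjusted p = 0.0302 and 0.0202, and 0.998 and 0.973 with an estimated correlation), until 1 of 8 or 1 of 2 further arrays was left out. Under E and F its means differed by −0.16 and 0.03 for MTX against healthy. Ribosomal protein genes had medians of −0.54, −1.02 and −0.46 in MTX against healthy, MTX+Et against healthy and MTX+Et against MTX, with adjusted p = 0.0123, 7.34e-05 and 6.78e-05, and with adjusted p = 0.968, 0.964 and 0.938 with an estimated correlation. Without that array their medians were −0.02, −0.02 and 0.00 and none was called. With MTX, platelet markers had a median of 0.17 (13 of 21 higher, adjusted p = 0.0423, and adjusted p = 0.968 with an estimated correlation) and basophil markers of 0.23 (9 of 10, adjusted p = 0.0485, and adjusted p = 0.968 with an estimated correlation), with 0.27 and 0.22 without the narrow-range array and neither called. With all arrays these calls ended without any of 15 and 22 arrays of every group. Glucocorticoid responsive genes had a median of −0.36 with MTX+Et against healthy once that array was left out (4 of 18 higher, adjusted p = 0.0158, and adjusted p = 0.973 with an estimated correlation), and of −0.58 with all arrays (7 fell, adjusted p = 0.0737). The call without the narrow-range array ended without the MTX+Et E array (−0.27, adjusted p = 0.108). Between the regimens, monocyte markers stood at −0.30, T cell markers at −0.21, regulatory T cell genes at 0.00 and oxidative phosphorylation genes at −0.25, with adjusted p = 0.0162, 0.0360, 0.0413 and 6.78e-05, each with adjusted p = 0.938 with an estimated correlation. Without the narrow-range array they stood at −0.06, −0.01, 0.05 and −0.01. Of these the regulatory T cell genes alone were called (adjusted p = 0.0166, and adjusted p = 0.398 with an estimated correlation). That call ended without 2 MTX H, 1 MTX+Et E or 1 MTX+Et H array singly. Another 4 lists were called between the regimens without that array, though not in the reported fit with all arrays. HLA class II genes stood at 0.09 (12 of 13 higher, adjusted p = 4.66e-05, and adjusted p = 0.398 with an estimated correlation) and basophil markers at −0.22 (1 of 10, adjusted p = 0.00108, and adjusted p = 0.430 with an estimated correlation). Glucocorticoid responsive genes stood at −0.08 (5 of 18, adjusted p = 0.00317, and adjusted p = 0.440 with an estimated correlation) and erythroid markers at −0.10 (5 of 17, adjusted p = 0.0362, and adjusted p = 0.857 with an estimated correlation). The glucocorticoid call ended without 1 MTX H or the MTX+Et E array. That of erythroid markers ended without any of 12 arrays (1 MTX E, 4 MTX H, 1 MTX+Et F and 6 MTX+Et H).

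Other gene lists were called in no comparison in the reported fit with all arrays: dendritic cell, eosinophil and cell cycle markers, neutrophil granule precursors, TNF ligands and receptors, adenosine metabolism, innate sensing, oxidant defence, immediate early genes, and hypoxia and glycolysis. Of these, neutrophil granule precursors (−0.33) and immediate early genes (0.09) were called between the regimens in PBMC without the narrow-range array, with adjusted p = 0.000123 and 0.0126, and with adjusted p = 0.398 and 0.763 with an estimated correlation. The first call ended without 1 MTX H array (−0.13, adjusted p = 0.123) and the second without any of 7 arrays of the regimens. Other settings with all arrays called some of them. In granulocytes, the replicate block called eosinophil markers in MTX+Et against healthy at 0.67 (13 of 14 higher, adjusted p = 0.0209, and adjusted p = 0.729 with an estimated correlation) and against MTX at 0.43 (14 of 14, adjusted p = 0.0291, and adjusted p = 0.695 with an estimated correlation). It also called immediate early genes there at −0.38 and −0.23 (adjusted p = 0.0215 and 0.0207, and 0.729 and 0.640 with an estimated correlation). Innate sensing genes were called with the block between the regimens, at −0.13 (adjusted p = 0.0275, and adjusted p = 0.695 with an estimated correlation). With no filter on dim genes, immediate early genes were called in PBMC of MTX against healthy at −0.23 (adjusted p = 0.0192, and adjusted p = 0.819 with an estimated correlation). TNF ligands and receptors (−0.24) and innate sensing genes (−0.19) were called that way in MTX+Et against healthy PBMC, each with adjusted p = 0.0341, and with adjusted p = 0.724 with an estimated correlation. Between the regimens in PBMC it called granule precursors (−0.33), oxidant defence (−0.15) and hypoxia genes (−0.10). Their adjusted p were 0.00459, 0.00750 and 0.00798, and each 0.649 with an estimated correlation. Without the letter term, innate sensing genes were called in granulocytes of MTX against healthy at 0.09 (adjusted p = 0.0249, and adjusted p = 0.976 with an estimated correlation). Granule precursors were called in PBMC of MTX against healthy at 0.34 (10 of 10 higher, adjusted p = 0.00447, and adjusted p = 0.943 with an estimated correlation). BCKDK, a kinase that restrains breakdown of branched amino acids, was chosen after its values were seen. With MTX+Et it fell by 0.60 in granulocytes (adjusted p = 0.0237) and rose by 0.38 in PBMC (adjusted p = 0.0435), a difference of 0.97 (SE 0.18, limma adjusted p = 0.00447), which was 0.99 without the narrow-range array, where the PBMC value of 0.39 did not pass (adjusted p = 0.0692).

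Each count of called genes was set against other splits of the same samples into groups of the same sizes, 100 in each case with the real one, or all 72 for splits within letters of MTX+Et against healthy PBMC without the narrow-range array. In splits over all samples, no other split reached the count for PBMC MTX against healthy (260 genes, highest other 1) or MTX+Et against healthy (1776, highest other 1). The same held without the narrow-range array (1233 and 843, highest others 6 and 10). Such splits move patient H arrays into the healthy group, which holds none. They do not keep the design and cannot exclude chance by themselves. For granulocytes of MTX+Et against healthy (79 genes) 3 splits reached the count, with the real one, and the highest other gave 429. Such tests were not adjusted for their number, so this does not exclude chance. For granulocytes of MTX against healthy (2 genes) it cannot be excluded: 3 splits over all samples reached that count, with a highest other of 3, and 5 of 100 drawn within letters, with a highest other of 14. Chance cannot be excluded either for MTX+Et against MTX in PBMC with all arrays. Its 1 gene was reached by 7 splits over all samples (highest other 4) and by 5 of 100 within letters (highest other 78). The same holds without the narrow-range array. There 3 splits over all samples reached the 1 gene, with a highest other of 39. Within letters 4 of 100 did, with a highest other of 46. A count of 0 is reached by all 100 splits and says nothing about chance. That applies to MTX+Et against MTX in granulocytes, with a highest other of 461 over all samples and of 0 within letters. It applies also to the interactions of MTX against healthy (220 over all samples, 1758 within letters) and of MTX+Et against MTX (36 and 53). Splits drawn within each letter keep the letters of each group. Counting the real one, 2 of 100 reached the 260, 2 the 1776 and 2 the 1233, with highest others of 468, 1889 and 1814. The real split alone reached the 79 (highest other 38) and the 843 (highest other 820). These values make chance less likely for these counts but do not exclude it, as the tests were not adjusted for their number. What the splits with large counts share was not tested.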
